A study of Homo sapiens with 12 samples.

How the data were processed

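RNA from 12 dishes of human prostate cancer cells was measured by RNA sequencing in 4 groups of 3 libraries. C4-2 cells carried a control lentivirus or one expressing ARv7, and 22Rv-1 cells carried a control short hairpin or one against ARv7. Per the labels, cells were plated in triplicate dishes, lysed in TRIzol and sequenced on an Illumina NovaSeq instrument, and reads were trimmed with Cutadapt 2.7 to remove poly(A) and unqualified reads. The aligner, the counting tool and the strand of the libraries are not given in the sources used here. Reads from antisense or overlapping genes could therefore not be separated.

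The deposited table gave raw read counts per gene, whole numbers with no normalization. It also gave FPKM, read counts that the authors scaled to gene length and library total. The table held 19974 lines. One line lacked a gene identifier because an annotation had broken over it, which left 19973 genes. The labels name the build hg18. Of the gene identifiers, 19876 were found in GENCODE release 29 on GRCh38, and 19865 of these had start or end within 10000 bp of it, 9000 of them with both the same. Coordinates are therefore given as the table has them, which is GRCh38. Of the genes, 19839 were protein-coding in that release. Another 97 identifiers were not in it.

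Total counts ran from 12318529 to 14672948 per library. A gene with 3 counts in a library stood at 0.204 to 0.244 CPM, read counts scaled to a common library total. Intervals and floors cover counting error only, because PCR copies of a molecule were not told apart.

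Each cell line was compared on its own with edgeR 4.0.16: filterByExpr with the group, TMM normalization, glmQLFit and the quasi-likelihood F-test, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. This tested 12783 genes in C4-2 and 13459 in 22Rv-1. The biological coefficient of variation was 0.065 in C4-2 and 0.052 in 22Rv-1. A fit of all 12 libraries with 4 groups tested whether the response of a gene differed between the lines. CPM values in the text are TMM-normalised within a line unless said otherwise, so levels should not be set side by side between lines. A gene with 0 counts in a group was given a bound from a floor of 3 counts over the group. A gene with few counts in a group was given the ratio of CPM with an exact 95% counting interval. These bounds and ratios use total counts with no scaling factor, so they differ from the quotient of the TMM-normalised levels.

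A set of 44 gene lists, 856 genes of which 854 were in the table, covered DNA repair, the cell cycle, stress, metabolism, signalling, lineage and markers of other cells. Lists with at least 5 tested members were tested with camera in limma 3.58.1 at a preset correlation of 0.01, on log2 CPM with a prior count of 2, two-sided, adjusted over lists. Camera with an estimated correlation and fry were run beside it. The groups, comparisons, tests, lists, naming rule and most alternative settings were written before the data were examined.

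The rule for named genes took the 10 largest rises and 10 largest falls in log2 fold change per comparison. These came from genes past the threshold with a mean of at least 5 CPM, a gene symbol and no overlap between groups. From each list it took up to 4 members with the smallest adjusted p, and members that moved against the rest. It also took the 10 genes with the largest opposite changes in both comparisons, ranked by the smaller of the log2 changes. Some genes and lists that the rule took are not reported here.

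Calls of the comparisons that went in the same or in opposite directions were counted among 12080 genes tested in both, with a two-sided Fisher's exact test of each overlap. The comparisons shared no library. The alternatives were DESeq2 1.42.0, its size factors in edgeR, no filter on low counts, a mean of at least 5 CPM, a replicate block, 1 fit of all libraries, and glmTreat against a fold of 1.2. Limma with a trend on log2(FPKM + 1), kept at a mean of at least 1, and leaving out each library in turn were also run. Total counts with no scaling factor, libraries without ribosomal protein and mitochondrially encoded genes, and repair lists without cell-cycle-linked members were added after seeing the data. A smaller pseudocount on FPKM was meant only for a table without counts and was not run.

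The pipeline was tested on simulated data with 3 libraries per group, with 50 genes at each fold. It recovered 42% of genes changed 1.2-fold, 84% at 1.5-fold, 96% at 2-fold and 100% at 4-fold in the C4-2 setting, and 2.8% of calls were unchanged genes. In the 22Rv-1 setting it recovered 32%, 88%, 94% and 100%, and 4% of calls were unchanged genes. For the difference between lines it recovered 12%, 58%, 78% and 94%. Far fewer genes changed there than in the real data, with 179 of 12480 genes called in the C4-2 setting and 177 of 13148 in the 22Rv-1 setting. The adjusted threshold was therefore stricter. The simulated spread was the same for every gene and below the biological coefficient of variation of either line, which makes recovery easier. A rate below 100% at 4-fold in either line would have stopped the run, so that value could not come out otherwise. These rates need not carry over to the real fits. The work used R 4.3.3, Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.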

Results

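Expression was measured by RNA sequencing in C4-2, a castration-resistant derivative of the LNCaP prostate cancer line, and in 22Rv-1, a prostate cancer line derived from the CWR22R xenograft. ARv7 is a splice variant found in prostate cancer. C4-2 cells expressed ARv7 from a lentivirus and 22Rv-1 cells were depleted of it by a short hairpin, each beside control cells of the same line. Each of the 4 groups had 3 libraries. Total read counts were 14576092, 14672948 and 14447244 in the C4-2 control libraries and 14634365, 13938661 and 12318529 with ARv7. They were 14354671, 13136228 and 14632128 in the 22Rv-1 control libraries and 13110248, 12863379 and 13929454 after depletion. Levels are in CPM, read counts scaled to a common library total.

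Cell line separated the libraries along the first principal component, which held 84% of the variance. The C4-2 groups separated on the second, with 7.3%, and the 22Rv-1 groups on the third, with 4.4%. Cells were puromycin-selected and plated in triplicate dishes, and how many lines were selected per group is not given in the sources used here. All p-values of single genes therefore measure only the spread between dishes, and any other difference between selected lines goes with the group. Exact and permutation tests take genes as the units and do not measure that spread. Replicates of every group differed by more than counting error alone gives. C4-2 control replicate 3 stood apart most, with a chi-square per degree of freedom of 13.9 and 7.62 against control replicates 1 and 2, where other pairs of replicates had 2.14 to 4.99.

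**Figure D1:**
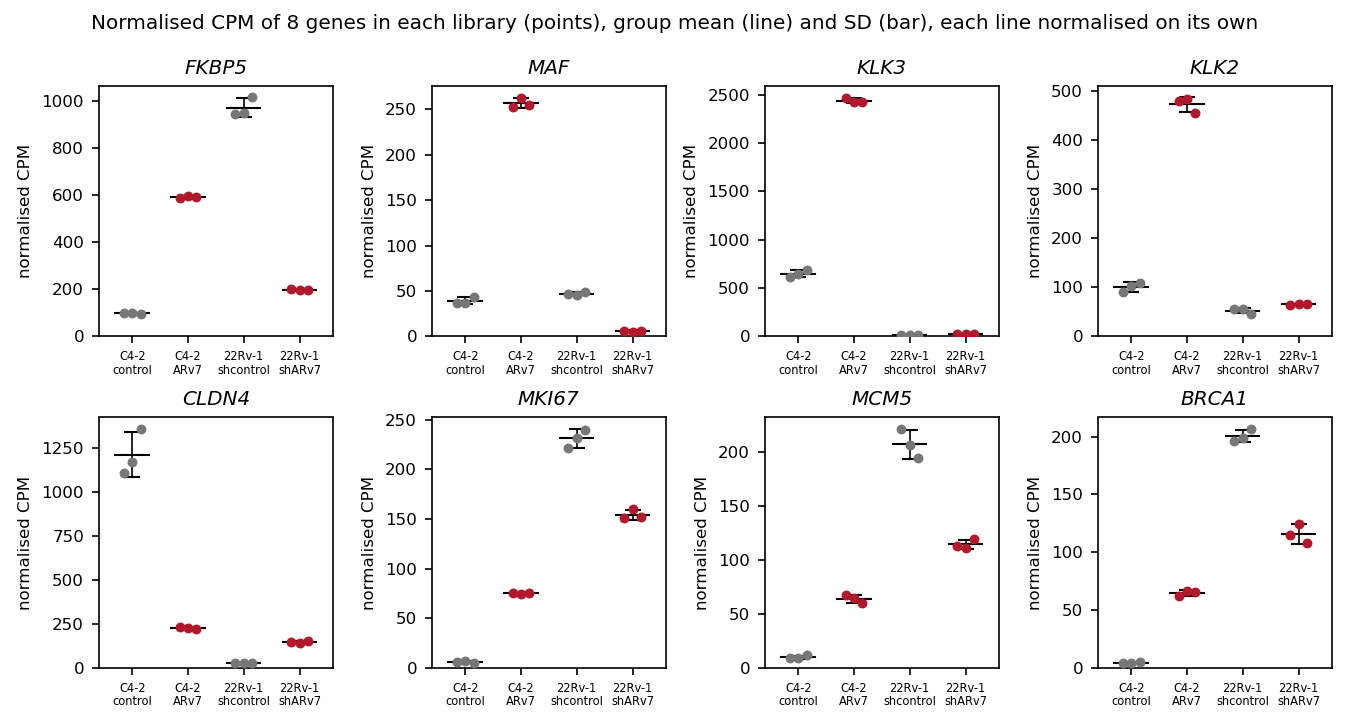
Normalised CPM (y axis, from 0, linear) of 8 genes in each of the 12 libraries, with points for libraries, lines for group means and bars for SD (n = 3), normalised within each cell line. FKBP5, MAF, MKI67, MCM5 and BRCA1 were higher with ARv7 in C4-2 and lower after depletion in 22Rv-1, CLDN4 went the other way, and KLK3 and KLK2 were higher in both.

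The C4-2 comparison asked which genes change when ARv7 is expressed. Genes of cell division were far higher in C4-2 cells with ARv7 than in control cells: all 35 tested mitosis and G2/M genes rose, at a median of 14.5-fold. TOP2A, the topoisomerase that untangles chromosomes in dividing cells, went from 1.62 ± 0.673 to 79.2 ± 2.57 CPM (SD, n = 3 in this and all later means), and MKI67, which encodes the Ki-67 proliferation marker, from 5.79 ± 0.879 to 75.3 ± 0.451. FKBP5, a co-chaperone of steroid receptors, rose from 97.3 ± 3.17 to 590.5 ± 4.27 CPM. BRCA1, a homologous recombination gene on chromosome 17 (43044295 to 43170245), went from 4.58 ± 0.242 to 64.7 ± 2.39 CPM. Lists of ribosomal protein genes, p53 targets and integrated stress response genes were lower by camera, with 39 of 40, 15 of 28 and 16 of 23 genes falling. None of these calls held with an estimated correlation (camera adjusted p = 0.444, 0.203 and 0.444), and the p53 call was lost without ARv7 replicate 3 (camera adjusted p = 0.0515).

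Of the 35 tested genes of DNA replication and G1/S, 30 rose, 1 fell and 4 did not pass, with a median of 2.52-fold. RRM2, a subunit of ribonucleotide reductase, rose 18.4-fold, from 5.18 ± 0.148 to 95.3 ± 2.38 CPM. CDC6, which licenses replication origins, rose 10.1-fold, and the replicative helicase subunits MCM4 and MCM5 rose 4.46-fold and 6.56-fold. TK1, a thymidine kinase, fell by 0.27 on the log2 scale with TMM, a call lost with total counts (edgeR adjusted p = 0.101) and in limma on log2(FPKM + 1) (adjusted p = 0.0741). In the mitosis list CENPF, a centromere protein, rose 14.5-fold and KIF2C, a microtubule depolymerase, 16.6-fold. Camera gave adjusted p = 3.97e-18 for mitosis and 2.17e-12 for replication. Both calls held with an estimated correlation (camera adjusted p = 0.0442 for each).

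DNA repair and checkpoint genes moved less evenly. Of 32 tested homologous recombination genes 24 rose and 2 fell (camera adjusted p = 4.08e-07; adjusted p = 0.138 with an estimated correlation). POLQ, a polymerase of end joining by microhomology, rose 18.5-fold and XRCC2, a recombination protein, 7.07-fold. BRIP1, a helicase partner of BRCA1, went from 0.43 ± 0.252 to 18.9 ± 2.17 CPM. By total counts with no scaling factor, as for all ratios with a counting interval, its ratio was 48.1 (30.3 to 81.7). MUS81, a structure-specific nuclease, and RAD52, a strand-annealing protein, fell (log2 -0.59 and -0.29). RAD52 had edgeR adjusted p = 0.122 without control replicate 1, and 0.0699 and 0.0782 without ARv7 replicates 2 and 3. Of 24 checkpoint genes 16 rose and 2 fell (camera adjusted p = 0.000188; adjusted p = 0.144 with an estimated correlation). WEE1, a kinase that restrains CDK1, rose 7.54-fold, CHEK1, the checkpoint kinase below ATR, 3.52-fold, and CLSPN, its adaptor, had a ratio of 19.0 (13.2 to 28.5). ATM, the kinase that senses double-strand breaks, and RNF168, a histone ubiquitin ligase, fell (log2 -0.37 and -0.23). RNF168 had edgeR adjusted p = 0.0742 without control replicate 1, and 0.084 and 0.109 without ARv7 replicates 2 and 3. The falls of RAD52, ATM and RNF168 also depended on the scaling. With total counts their log2 changes were -0.14, -0.22 and -0.08 (edgeR adjusted p = 0.278, 0.063 and 0.41), and limma on log2(FPKM + 1) gave adjusted p = 0.27, 0.184 and 0.404. DESeq2 gave adjusted p = 0.0508 for RAD52.

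Of 14 mismatch repair genes 9 rose and 0 fell (camera adjusted p = 0.00108; adjusted p = 0.203 with an estimated correlation). They included the nuclease gene EXO1, with a ratio by total counts of 48.6 (28.2 to 91.8). EXO1 is also on the recombination list and PCNA also on the replication list. Of 17 Fanconi anaemia genes 9 rose and 2 fell (camera adjusted p = 0.00672; adjusted p = 0.203 with an estimated correlation). FANCI and FANCD2, the pair that is ubiquitinated at stalled forks, rose 4.27-fold and 4.88-fold. FANCF, a core complex subunit, and USP1, which removes that ubiquitin, fell (log2 -0.20 and -0.19). Neither call held in every fit without 1 library. FANCF had edgeR adjusted p = 0.0719 without control replicate 3, and 0.0931 and 0.0787 without ARv7 replicates 2 and 3. USP1 had 0.0836 and 0.163 without control replicates 1 and 2, and 0.0959 and 0.236 without ARv7 replicates 2 and 3 (edgeR adjusted p). Both falls also depended on the scaling, with log2 -0.06 and -0.04 by total counts (edgeR adjusted p = 0.528 and 0.683) and limma adjusted p = 0.45 and 0.699 on log2(FPKM + 1). USP1 had DESeq2 adjusted p = 0.0564 and, among genes with a mean of at least 5 CPM, edgeR adjusted p = 0.0663. Without their cell-cycle-linked members, none of these 4 lists passed (camera adjusted p = 0.17 for recombination, 0.388 for checkpoint, 0.248 for mismatch repair and 0.337 for Fanconi anaemia). Shorter lists are harder to call, so this loss does not show that the remaining members were unchanged. Over all repair and checkpoint lists, 37 of the 91 tested genes not linked to the cycle rose and 15 fell. Base excision repair, with 10 rising and 3 falling of 20, had camera adjusted p = 0.0733. Non-homologous end joining, with 9 rising and 2 falling of 17, had 0.197. Nucleotide excision repair, with 5 rising and 5 falling of 20, had 0.857.

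KLK3, which encodes prostate-specific antigen, went from 650.3 ± 39.3 to 2439 ± 25.3 CPM. Of 10 genes reported as induced by ARv7, 7 rose and 3 fell (camera adjusted p = 0.0332; adjusted p = 0.398 with an estimated correlation). CDK1, the mitotic kinase, rose 4.01-fold, MELK 20.4-fold and CDC20 8.29-fold. Of this list, 5 genes are also on the mitosis list, where every tested gene rose. SLC3A2, an amino acid transporter chain, ETS2, a transcription factor, and EDN2, an endothelin, fell (log2 -0.82, -0.60 and -1.36). The 3 that fell are not on the mitosis list. The call may therefore rest on the shared genes, and the list was not tested without them.

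Of 20 interferon response genes 10 rose and 2 fell (camera adjusted p = 0.0313; adjusted p = 0.203 with an estimated correlation). OAS3, an antiviral oligoadenylate synthetase, rose 8.78-fold and HERC5, the ligase for ISG15, 2.92-fold. DDX58, an RNA sensor, and IRF7, an interferon regulator, fell (log2 -0.85 and -0.34), the latter with edgeR adjusted p = 0.0867 without ARv7 replicate 2, 0.132 with total counts and limma adjusted p = 0.122 on log2(FPKM + 1). Of 28 p53 targets 15 fell and 4 rose (camera adjusted p = 0.0332, and 0.0515 without ARv7 replicate 3; adjusted p = 0.203 with an estimated correlation). TP53INP1, ZMAT3 and GDF15 fell (log2 -1.23, -1.07 and -1.02). GADD45A, a growth arrest gene, the death receptor genes TNFRSF10B and FAS and the antiproliferative gene BTG2 rose (log2 1.11, 0.66, 0.61 and 0.32). FAS lost its call without control replicate 2 or 3 (edgeR adjusted p = 0.0747 and 0.0876) or ARv7 replicate 3 (0.106), and in DESeq2 (adjusted p = 0.0742).

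Of 23 integrated stress response genes 16 fell and 2 rose (camera adjusted p = 0.00542; adjusted p = 0.444 with an estimated correlation). PSAT1 and PHGDH, enzymes of serine synthesis, fell (log2 -1.17 and -1.10), and so did STC2, a secreted stress protein, 2.24-fold. ATF3, a stress-induced factor, and SLC7A5, an amino acid transporter, rose (log2 0.93 and 0.65). Of 23 cholesterol synthesis genes 13 fell and 5 rose (camera adjusted p = 0.0358, and 0.0602 without ARv7 replicate 1; adjusted p = 0.444 with an estimated correlation). INSIG1, which retains the sterol sensor in the endoplasmic reticulum, and SREBF2, the master regulator of the pathway, fell (log2 -1.31 and -0.74). The enzyme genes TM7SF2, SQLE, FDPS and CYP51A1 were among those that rose (log2 0.51, 0.45, 0.29 and 0.53). The last 2 calls were fragile. FDPS had edgeR adjusted p = 0.0615 and 0.0944 without control replicates 1 and 3, and 0.173 and 0.0647 without ARv7 replicates 2 and 3. CYP51A1 had 0.118 and 0.0853 without control replicates 1 and 2, and 0.164, 0.0722 and 0.0511 without ARv7 replicates 1, 2 and 3 (edgeR adjusted p). DESeq2 gave adjusted p = 0.0748 and 0.122 for the pair, and CYP51A1 also lost its call with no filter on low counts (edgeR adjusted p = 0.0502) and with a replicate block (0.0661).

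Of 40 ribosomal protein genes 39 fell and 0 rose (camera adjusted p = 3.08e-10; adjusted p = 0.444 with an estimated correlation), for example RPS6 from 3361 ± 193.9 to 1952 ± 22.5 CPM. Of 13 mitochondrially encoded genes 12 fell and 0 rose (camera adjusted p = 0.000188; adjusted p = 0.444 with an estimated correlation), for example MT-ND1 from 2488 ± 241 to 1367 ± 63.7 CPM. These classes took different shares of the libraries of the groups. Mitochondrially encoded genes held 4.36% ± 0.295 of the counts in control libraries and 3.39% ± 0.114 with ARv7. Ribosomal protein genes held 6.75% ± 0.515 and 5.31% ± 0.049, and the 50 most abundant genes 15.8% ± 1.05 and 13.4% ± 0.102. Control replicate 3 had the highest shares, 4.66% mitochondrially encoded and 7.31% ribosomal. Without it camera adjusted p was 9.9e-11 for ribosomal and 0.000364 for mitochondrially encoded genes. The remaining 26 of the 40 tested lists did not pass, with camera adjusted p from 0.0733 to 0.948, and 4 lists of other cells had under 5 tested members. Adjusted over the list alone, the counts were the same for the called lists described here except 1 more falling gene each in the cholesterol, ribosomal and mitochondrial lists (14, 40 and 13).

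The largest rises in C4-2 included the acute-phase protein genes ORM1, from 0.074 ± 0.075 to 39.9 ± 2.67 CPM (ratio by total counts 609.5, counting interval 208 to 2958), and ORM2 (ratio 67.2, 33.8 to 156.5). The keratin gene KRT6C had a ratio of 143 (60.9 to 441) and the scaffold gene AKAP12 of 77.6 (52.8 to 119). UBE2C, a ubiquitin-conjugating enzyme of the anaphase-promoting complex, had 78.0 (40.8 to 171). The other large rises were in the mitotic and replication genes SKA1, TICRR, NEK2, PIMREG and CEP55, with ratios from 60.8 to 70.1. SLC6A12, a betaine transporter, went from 63.6 ± 6.05 CPM to 0 counts, at least 821-fold lower by total counts with a floor of 3 counts over the group. The lectin receptor gene KLRG1 went from 96.7 ± 10.5 to 0.286 ± 0.165 CPM. CYP11A1, which makes pregnenolone from cholesterol, fell from 91.5 ± 10.4 to 0.868 ± 0.235 CPM, 105-fold lower. SERPINA5, ST3GAL6, CLEC7A, CLIP2, RANBP3L, FBN1 and SERPINE2 made up the rest, the last 19.3-fold lower. Reads of close paralogs (ORM1 and ORM2, the KRT6 family, KLK2 and KLK3, UGT2B genes, HLA genes, ribosomal proteins and their pseudogenes) may be shared in part.

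Among markers of other cells, PDGFRB stood at 0.32 CPM (by total counts) in control and 4.41 with ARv7, VWF at 3.34 and 8.47, UPK3A at 1.17 and 8.56, and ESAM at 10.1 and 2.06. In all, edgeR called 7557 of 12783 genes (59.1%), 3781 higher and 3776 lower, and 1693 of them at least 2-fold, 1089 higher and 604 lower. Of the calls 50% were higher with TMM and 67.2% with total counts and no scaling factor, which moved the median of all genes from 0.005 to 0.152 on the log2 scale. All changes are relative to that scaling. Median log2 changes of p53 targets, stress response and cholesterol synthesis genes were -0.29, -0.29 and -0.27 with TMM. With total counts they were -0.14, -0.14 and -0.12. The numbers of falling genes given for these lists are those with TMM.

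The 22Rv-1 comparison asked which genes change when ARv7 is depleted. Genes of DNA replication were lower in depleted cells: 31 of 35 tested replication and G1/S genes fell, at a median of 1.44-fold lower. MCM5 fell from 208 ± 13.6 to 115 ± 4.22 CPM and MCM4 from 673 ± 13.5 to 425 ± 9.23. FKBP5 fell from 970 ± 40.7 to 199 ± 2.49 CPM, 4.87-fold lower, and BRCA1 fell 1.73-fold. IGFBP3, a binding protein of insulin-like growth factors (chromosome 7, 45912245 to 45921874), rose from 22.1 ± 1.44 to 398 ± 5.96 CPM. FN1, the extracellular matrix protein fibronectin, rose from 61.9 ± 5.32 to 712 ± 28.7 CPM.

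None of the 35 replication genes rose and 4 did not pass (camera adjusted p = 8e-12, and 0.0437 with an estimated correlation). UHRF1, which maintains DNA methylation at replication, fell by 0.82 on the log2 scale. Of 36 mitosis and G2/M genes 27 fell and 0 rose, at a median of 1.26-fold lower (camera adjusted p = 1.43e-07; adjusted p = 0.203 with an estimated correlation). FOXM1, a transcription factor of G2/M genes, MKI67 and the checkpoint kinase BUB1B fell (log2 -0.70, -0.58 and -0.54).

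Of 33 homologous recombination genes 24 fell and 1 rose (camera adjusted p = 4.32e-07; adjusted p = 0.196 with an estimated correlation). NBN, of the complex that senses double-strand breaks, XRCC2 and RBBP8, which starts end resection, fell (log2 -0.72, -0.73 and -0.60). BARD1, the ubiquitin ligase partner of BRCA1, rose (log2 0.29; edgeR adjusted p = 0.0552 without control replicate 1). Of 17 Fanconi anaemia genes 9 fell and 0 rose (camera adjusted p = 0.000475; adjusted p = 0.138 with an estimated correlation), with FANCI and FANCD2 at log2 -0.56 and -0.53. Of 24 checkpoint genes 14 fell and 2 rose (camera adjusted p = 0.000859; adjusted p = 0.203 with an estimated correlation). TIMELESS, a fork protection protein, and the phosphatase CDC25A fell 1.85-fold and 1.94-fold, while CDC25B, another phosphatase, and RNF8, a ubiquitin ligase, rose (log2 0.24 and 0.31). Of 14 mismatch repair genes 10 fell and 0 rose (camera adjusted p = 0.00185; adjusted p = 0.323 with an estimated correlation), among them PCNA, the replication clamp, and RFC3, of its loader (log2 -0.50 and -0.61). Without cell-cycle-linked members the Fanconi anaemia, checkpoint and mismatch repair lists did not pass (camera adjusted p = 0.0708, 0.421 and 0.421), and the recombination list did (0.0144). Here too the shorter lists were harder to call. Base excision repair, with 2 rising and 8 falling of 20, had camera adjusted p = 0.124. Non-homologous end joining, with 3 rising and 6 falling of 17, had 0.542, and nucleotide excision repair, with 3 rising and 5 falling of 20, had 0.799.

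KLK3 rose from 15.5 ± 1.2 to 24.3 ± 2.99 CPM and its paralog KLK2 from 52.0 ± 4.82 to 65.3 ± 1.28. Of 10 genes reported as induced by ARv7, 6 fell and 1 rose (camera adjusted p = 0.0179; adjusted p = 0.203 with an estimated correlation). SLC3A2 fell by 0.60 on the log2 scale and EDN2 rose (log2 0.66). This list shares 5 genes with the mitosis list and was not tested without them. Of 23 integrated stress response genes 19 fell and 0 rose (camera adjusted p = 4.32e-07; adjusted p = 0.0696 with an estimated correlation). SLC7A5, PHGDH and the stress-induced SESN2 fell 1.72-fold, 1.85-fold and 1.79-fold. Of 12 neuroendocrine markers 7 fell and 1 rose (camera adjusted p = 0.00234; adjusted p = 0.203 with an estimated correlation). The splicing regulator SRRM4, the neuronal enolase ENO2 and SNAP25 fell (log2 -0.83, -0.76 and -0.83), and DLL3, a Notch ligand, rose (log2 0.63; edgeR adjusted p = 0.142 without control replicate 2 and 0.0764 without depleted replicate 2; DESeq2 adjusted p = 0.0662).

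Antigen presentation genes were higher, with 6 rising and 0 falling of 14 (camera adjusted p = 0.00373; adjusted p = 0.196 with an estimated correlation). The class I genes HLA-C, HLA-E and HLA-B rose (log2 1.35, 0.82 and 1.80), and so did the peptide transporter TAP1 (log2 0.71). Of 14 heat shock genes 10 rose and 0 fell (camera adjusted p = 0.00373; adjusted p = 0.247 with an estimated correlation), with HSPB1 from 256 ± 13.4 to 478 ± 11.5 CPM. Of 19 endoplasmic reticulum chaperones 11 rose and 2 fell (camera adjusted p = 0.0217; adjusted p = 0.247 with an estimated correlation). HSPA5, the main luminal chaperone, rose 1.7-fold, and HYOU1, a co-chaperone, and SEL1L, of the degradation complex, fell (log2 -0.29 and -0.30). Of 12 WNT pathway output genes 7 rose and 3 fell (camera adjusted p = 0.034; adjusted p = 0.219 with an estimated correlation). DKK1 and BAMBI, which restrain WNT and TGF-beta signalling, rose 6.95-fold and 6.3-fold, while CCND1, a cyclin, TCF7, a transcription factor, and LGR5, a stem cell receptor, fell (log2 -0.14, -0.58 and -0.93). TCF7 had edgeR adjusted p = 0.108 without control replicate 2 and 0.0946 without depleted replicate 1. LGR5 had 0.191 and 0.205 without control replicates 1 and 3, and 0.225 and 0.26 without depleted replicates 2 and 3 (edgeR adjusted p). DESeq2 gave adjusted p = 0.0554 for TCF7 and 0.193 for LGR5, and edgeR in 1 fit of all libraries 0.0802 and 0.121. LGR5 also lost its call with total counts (edgeR adjusted p = 0.0581). Of 40 ribosomal protein genes 30 rose and 0 fell (camera adjusted p = 0.000198; adjusted p = 0.506 with an estimated correlation), each by little (median log2 0.14).

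The lists that follow were called and each lost the call when 1 library was left out and with a replicate block (camera adjusted p = 0.0858 for mitochondrially encoded genes and 0.0624 for each other list). Oxidative phosphorylation genes (11 rose and 1 fell of 32; camera adjusted p = 0.045) reached 0.0598, 0.0707 and 0.105 without control replicates 1, 2 and 3, and 0.12 and 0.0816 without depleted replicates 1 and 3. Prostate luminal markers (9 rose and 3 fell of 14; camera adjusted p = 0.045) reached 0.0766 and 0.0723 without control replicates 2 and 3, and 0.0573 and 0.0587 without depleted replicates 1 and 3. The keratins KRT19 and KRT8 rose, and STEAP1 and SPDEF were among those that fell (log2 0.78, 0.56, -1.22 and -0.18), the last with edgeR adjusted p = 0.148 without depleted replicate 1, 0.0529 with total counts and limma adjusted p = 0.0667 on log2(FPKM + 1). Immediate early genes (12 rose and 4 fell of 23; camera adjusted p = 0.045) reached 0.0876 without control replicate 3, and 0.0658 and 0.0503 without depleted replicates 1 and 3. JUNB and DUSP1 rose, and ATF3, JUN, KLF4 and KLF6, transcription factors, fell (log2 0.87, 0.81, -0.33, -0.28, -0.37 and -0.42). Glucocorticoid-induced genes (7 fell and 2 rose of 13; camera adjusted p = 0.0421) reached 0.0666 without control replicate 3 and 0.0734 without depleted replicate 3. ZBTB16 fell by 1.32 on the log2 scale, and DUSP1 and TSC22D3 rose, the latter with edgeR adjusted p = 0.0602 without control replicate 3 and 0.163 without depleted replicate 1. Mitochondrially encoded genes (9 fell and 1, MT-ND6, rose of 13; camera adjusted p = 0.045) reached 0.0601 without control replicate 3, and 0.0573, 0.0615 and 0.0503 without depleted replicates 1, 2 and 3. With an estimated correlation the lists had, in the order given, adjusted p = 0.501, 0.324, 0.336, 0.336 and 0.236.

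Adjusted over the list alone, counts of the called lists in 22Rv-1 differed as follows. In the mitochondrial list 2 genes rose, in the chaperone list 12 and in the oxidative phosphorylation list 10. Falling genes numbered 7 in the list reported for ARv7, 10 in Fanconi anaemia, 32 in replication, 29 in mitosis and 22 in the stress response. All other counts of the called lists described here were the same. The 21 lists that did not pass had camera adjusted p from 0.124 to 0.937, and 2 lists of other cells had under 5 tested members. Where no call was made, median, mean and test could differ in sign. This held for nucleotide excision repair, glycolysis, mesenchymal and steroid genes in C4-2, and for histone, fatty acid, cholesterol, oxidative stress and ribosome biogenesis genes in 22Rv-1.

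The largest rises in 22Rv-1 included PTGS2, the inducible cyclooxygenase, from 0.122 ± 0.046 to 30.5 ± 2.47 CPM (ratio by total counts 260.5, counting interval 111 to 804), and INHBA, an activin subunit (ratio 243, 104 to 750.5). The protocadherin gene PCDH19 had a ratio of 69.2 (33.3 to 173) and the lipase gene LPL of 59.2 (40.3 to 91.0). SMOC1, SEMA3D, CYFIP2, DNAJA4 and the phosphodiesterase gene PDE4B also rose, the last 16.3-fold. The nuclear receptor gene NR5A2 went from 19.9 ± 1.49 to 0.248 ± 0.051 CPM (ratio 78.3, 42.4 to 164). TMEFF2, a prostate membrane protein, fell 11.8-fold, the potassium channel gene KCNMA1 11.6-fold and the amino acid transporter gene SLC38A4 9.72-fold. RELN, an extracellular matrix protein, fell from 514 ± 13.7 to 65.7 ± 3.76 CPM, and GPM6A and CRISPLD1 fell as well.

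Among markers of other cells, the stromal proteoglycan genes LUM and DCN fell (22.9 ± 1.82 to 2.4 ± 0.679 and 2.42 ± 0.375 to 0.173 ± 0.116 CPM). The collagen genes COL3A1 and COL1A1 rose (log2 0.72 and 0.32), the latter with edgeR adjusted p = 0.0941 without depleted replicate 3. The stromal list had camera adjusted p = 0.378 and the urothelium and kidney list 0.162. By total counts, the leukocyte markers LYZ, PTPRC, CD14, TYROBP and CSF1R stood at 0.67, 0.12, 0.26, 0.07 and 0.33 CPM in control and 3.78, 1.08, 0.98, 0.45 and 0.73 after depletion, and the kidney marker PAX2 at 1.28 and 4.25. Mitochondrially encoded genes held 3.95% ± 0.023 of the counts in control libraries and 3.37% ± 0.049 after depletion, and ribosomal protein genes 4.68% ± 0.13 and 5.41% ± 0.153. In all, edgeR called 6467 of 13459 genes (48%), 3220 higher and 3247 lower, and 1029 of them at least 2-fold, 754 higher and 275 lower. With total counts and no scaling factor 58.5% of the calls were higher, against 49.8% with TMM. Across genes, log2 change and the gene length in the table had Spearman's rho = 0.104 in C4-2 and -0.126 in 22Rv-1. In a comparison chosen after seeing the data, the 100 other genes nearest in length to each ribosomal protein gene had a median log2 change of -0.04 in C4-2 and 0.04 in 22Rv-1, where ribosomal protein genes had -0.56 and 0.14.

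**Figure D2:**
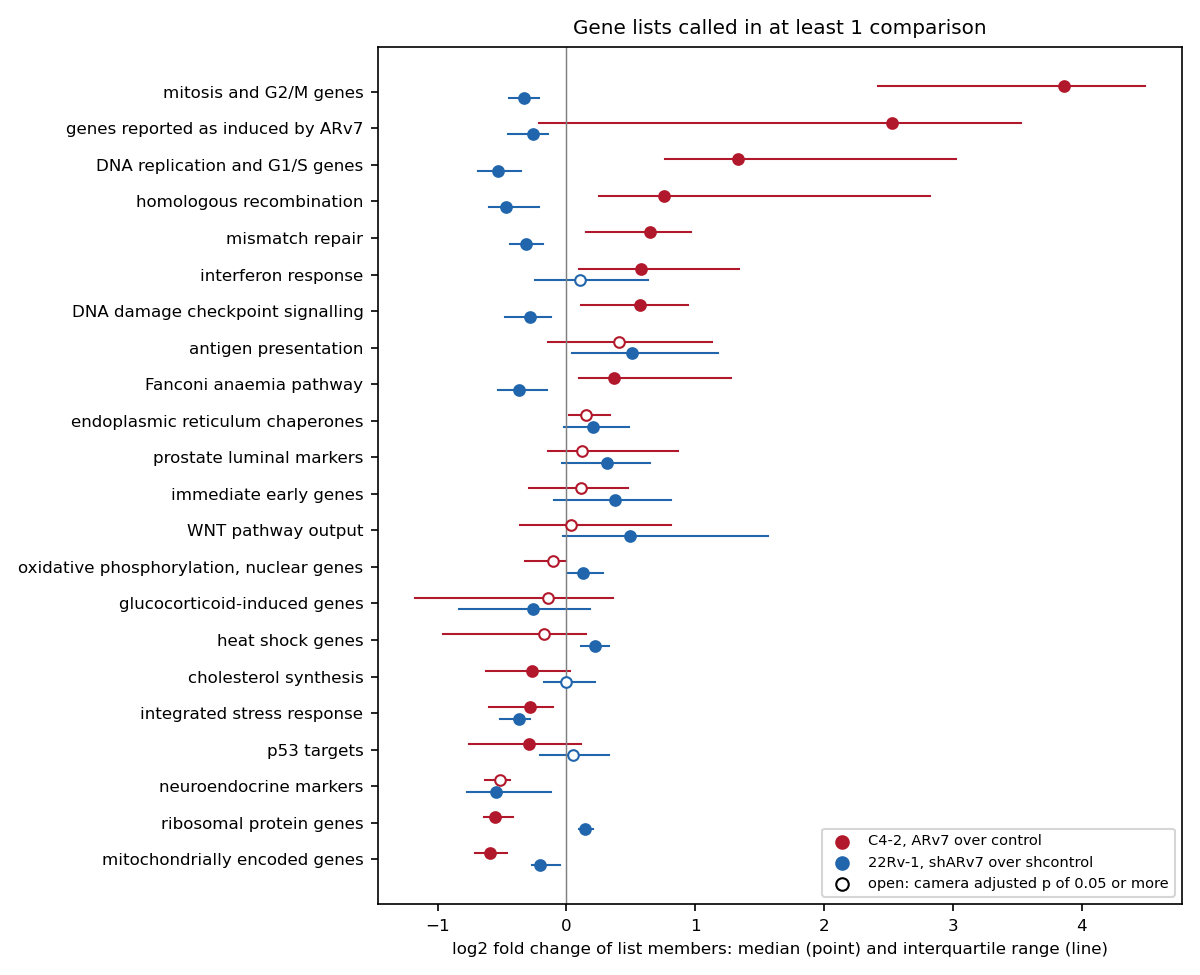
Median log2 fold change (points, x axis) and interquartile range (lines) of the members of lists called in at least 1 comparison, with C4-2 (ARv7 over control) in red and 22Rv-1 (depleted over control) in blue, and open points where camera adjusted p was 0.05 or more. Mitosis genes lay at 3.86 in C4-2 and -0.33 in 22Rv-1, and integrated stress response genes at -0.29 and -0.37; the medians of glucocorticoid-induced and oxidative phosphorylation genes in C4-2 and of cholesterol synthesis in 22Rv-1 changed sign with total counts.

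The comparisons were set side by side to ask which genes follow ARv7 when it is gained and when it is lost. FKBP5, MAF, ADAM7 and the amino acid transporter gene SLC38A4 rose with ARv7 in C4-2 and fell with depletion in 22Rv-1 (log2 2.60 and -2.29, 2.71 and -2.97, 3.54 and -1.99, 2.67 and -3.28). The proteoglycan gene SPOCK1 and the exchange factor gene SPATA13 did the same (log2 1.79 and -2.19, 1.64 and -2.21). CLDN4, a tight junction protein, fell in C4-2 from 1212 ± 128 to 226 ± 4.55 CPM and rose in 22Rv-1 from 27.4 ± 0.883 to 148 ± 5.68 CPM. LITAF, SYTL2 and the cholesterol exporter gene ABCG1 also fell in C4-2 and rose in 22Rv-1 (log2 -1.96 and 3.12, -1.99 and 1.80, -1.89 and 1.69).

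Of 12080 genes tested in both comparisons 3706 were called in both, 1999 in opposite directions (53.9%) and 1707 in the same direction. Genes higher with ARv7 and lower with depletion numbered 1139, against 885.7 by chance (two-sided Fisher's exact test, odds ratio 1.68, 1.54 to 1.83, p = 1.18e-30). Genes lower with ARv7 and higher with depletion numbered 860, against 835.8 (exact test, odds ratio 1.05, p = 0.258). Those higher in both numbered 844, against 830.3 (exact test, odds ratio 1.03, p = 0.524), and those lower in both 863, against 891.6 (odds ratio 0.94, p = 0.189). Among changes of at least 2-fold, 48 genes were higher with ARv7 and lower with depletion, against 12.6 (exact test, odds ratio 5.18, p = 1.53e-16). In the reverse order there were 60, against 18.2 (exact test, odds ratio 4.03, p = 1.41e-16). Another 68 were higher in both, against 36.1 (exact test, odds ratio 2.11, p = 3.24e-07), and 9 were lower in both, against 6.4 (odds ratio 1.45, p = 0.302). Genes are not independent replicates, so these p-values understate the chance of such overlaps. Across genes the log2 fold changes had Pearson's r = -0.101 and Spearman's rho = -0.072.

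**Figure D3:**
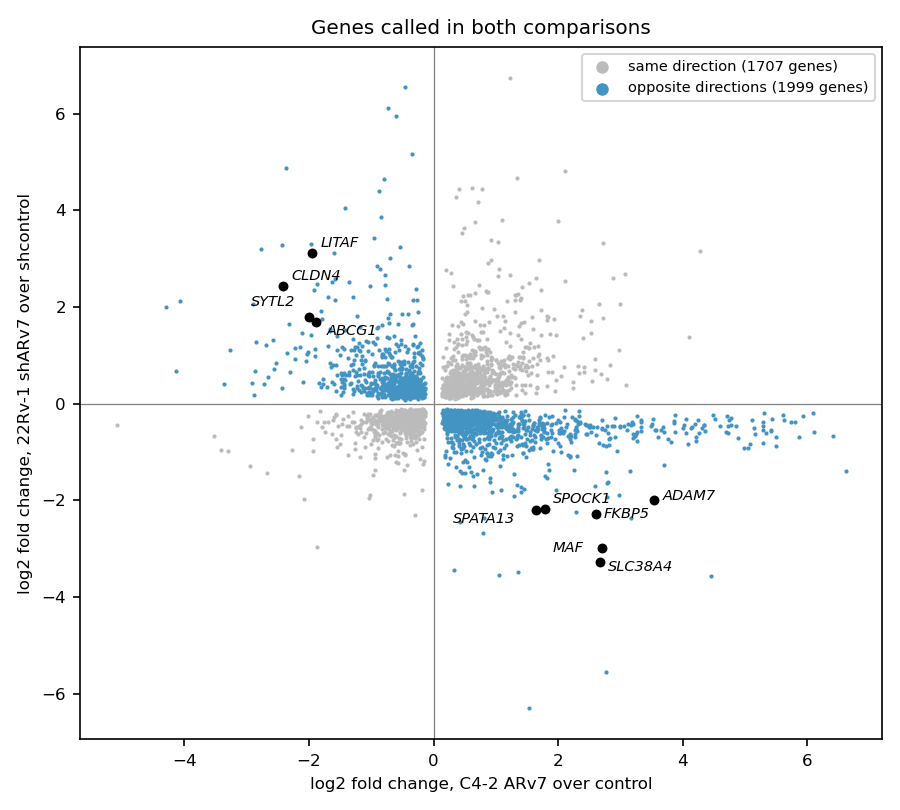
Log2 fold change in C4-2 (x axis, ARv7 over control) against 22Rv-1 (y axis, depleted over control) for the 3706 genes called in both comparisons, 1999 in opposite directions in blue and 1707 in the same direction in grey. The 10 genes named as the largest opposite changes are in black.

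The difference between the responses, the C4-2 change minus the 22Rv-1 change, passed the threshold in 7151 of 14235 genes (edgeR adjusted p), 3574 with a positive and 3577 with a negative difference. It was 4.90 on the log2 scale for FKBP5 (SE 0.0755; edgeR adjusted p = 9.25e-35), 5.70 for MAF (SE 0.121; 2.45e-30) and -4.84 for CLDN4 (SE 0.0943; 2.09e-31). These genes were named for large opposite changes, so the difference adds up both sizes and its p-values add nothing to that choice. The gain of ARv7 in one line and its loss in the other are opposite treatments, so the difference does not compare like with like. A gene that follows ARv7 alike in both lines also passes.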

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

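The tests of mixing and of repair genes were written before their results were seen, as were the splits of the libraries. Those of scaling and single libraries for mitosis genes, and those for KLK3 and KLK2, were chosen after the result was seen. Groups of 3 are too small for a test of a single outlying library.

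Among all genes, 1707 of the 3706 called in both comparisons moved the same way, so such genes are common. The genes below were sought only among members of a gene list fixed beforehand. Each of the following was flagged because it moved the same way in both comparisons, so that its effect aligned on the level of ARv7 differed between the lines. For a gene that difference is about the sum of its log2 changes, so a test of it adds nothing to the choice of items called the same way in both lines, and the p-values of the difference are given for completeness only. Integrated stress response genes were lower in both (median log2 -0.29 in C4-2, where 16 of 23 fell and 2 rose, and -0.37 in 22Rv-1), but neither call held with an estimated correlation (camera adjusted p = 0.444 and 0.0696). With total counts the stress response medians were -0.14 and -0.32. Mitochondrially encoded genes were lower in both (median log2 -0.60 and -0.20, and -0.45 and -0.16 with total counts), again not with an estimated correlation (camera adjusted p = 0.444 and 0.236). In 22Rv-1 that call was also lost with a replicate block (camera adjusted p = 0.0858), without control replicate 3 (0.0601) and without depleted replicates 1, 2 and 3 (0.0573, 0.0615 and 0.0503). KLK3 rose in both (log2 1.91 and 0.65), as did KLK2 (2.23 and 0.33), CENPN (1.36 and 0.77) and STEAP4 (2.98 and 1.11). PLPP1 was lower in both (-0.16 and -1.19), as were KLK4 (-0.52 and -0.12) and RAB3B (-0.66 and -0.75). For the difference, camera adjusted p was 5.76e-07 for stress response and 7.93e-06 for mitochondrially encoded genes. The edgeR adjusted p was 3.3e-21 for KLK3, 2.4e-22 for KLK2, 1.11e-18 for CENPN, 5.65e-06 for STEAP4, 4.5e-17 for PLPP1, 3.38e-09 for KLK4 and 3.57e-15 for RAB3B. Some of these gene calls were lost under other settings. PLPP1 in C4-2 had edgeR adjusted p = 0.0592 and 0.105 without ARv7 replicates 1 and 2, and its fall there depended on the scaling (log2 -0.01 with total counts, edgeR adjusted p = 0.836; limma adjusted p = 0.818 on log2(FPKM + 1)). So did the fall of KLK4 in 22Rv-1 (log2 -0.07 with total counts, edgeR adjusted p = 0.155; limma adjusted p = 0.138). In 22Rv-1 KLK4 had 0.11 without control replicate 1 and 0.054 without depleted replicate 1, and STEAP4 had 0.186, 0.053 and 0.0898 without control replicates 1, 2 and 3, and 0.216 and 0.0883 without depleted replicates 1 and 2 (edgeR adjusted p). STEAP4 in 22Rv-1 also lost its call in DESeq2 (adjusted p = 0.154) and in edgeR with DESeq2 size factors, no filter on low counts, a replicate block or 1 fit of all libraries (adjusted p = 0.0511, 0.105, 0.076 and 0.054).

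Mitosis genes were near absent in C4-2 control libraries, with a median of 1.84 to 1.97 CPM per library against 18.9 to 22.1 with ARv7 and 51.8 to 54.2 in 22Rv-1 control libraries, here with TMM over all 12 libraries. Admixed 22Rv-1 cells are argued against, since 57 genes abundant in 22Rv-1 and near absent in C4-2 control stood at a median of 0.649% (0.407 to 0.739) of their 22Rv-1 level in the ARv7 libraries, where mitosis genes stood at 45.5%, both by total counts; RGS2 and GIPR stood at 0.219% and 0.284%, and 7 of the 57 were over 10%. The choice among 3 scalings is argued against by a median log2 change of at least 3.855 under each. A single wrong or failed library is argued against by at least 3.76 without any 1 library. A biological hypothesis is that fewer cells were dividing in the control dishes, which could follow from ARv7, from cell density at harvest or from other differences between separately selected lines, all untested and open.

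Of 7 repair and checkpoint lists, 4 were called higher in C4-2 and lower in 22Rv-1 by camera, none with an estimated correlation (camera adjusted p from 0.138 to 0.203 in C4-2 and 0.138 to 0.323 in 22Rv-1). A candidate explanation is that repair genes moved as part of the cell cycle. In C4-2 the 91 genes not linked to the cycle had a median log2 change of 0.134 (0.049 to 0.209), 37 rising and 15 falling, and the 51 linked ones 1.197 (0.846 to 1.83), 44 rising and 1 falling (permutation p = 1e-05, the smallest that 100000 permutations give). In 22Rv-1 the 92 unlinked genes had a median of -0.125 (-0.162 to -0.041), 10 rising and 32 falling, and the 51 linked ones -0.484 (-0.543 to -0.429), 1 rising and 43 falling (permutation p = 1e-05). The recombination list there passed without linked members (camera adjusted p = 0.0144). The cycle may account for most of the C4-2 rise. The intervals of the unlinked genes exclude 0 in both lines, but they treat genes as independent. So do the permutation p-values, which do not measure the spread between dishes. A gene not listed as linked may also still follow the cycle. Whether the cycle accounts for all of the changes therefore stays open. Whether ARv7 acts on repair genes apart from the cycle was not tested.

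KLK3 and KLK2 rose in depleted 22Rv-1 cells as they did in C4-2 cells with ARv7. KLK2 reads counted as KLK3 are argued against as the whole cause of the KLK3 rise, which exceeded that of KLK2 by 0.324 on the log2 scale (SE 0.131). KLK3 reads counted as KLK2 stay open for the smaller KLK2 rise (log2 0.328), since partial sharing would give a diluted change. The choice among the scalings run is argued against by a log2 change of at least 0.321 for both under the other scalings (edgeR adjusted p at most 0.000124). Those scalings moved the median of all genes only from 0.009 to 0.002 and 0.056, so they could not test a larger shift. A hypothesis is that other differences between separately selected lines may have moved KLK3 and KLK2, which was not tested.

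The 6 libraries of a comparison give 10 splits, too few for a share under 0.05. Every split but the real one mixes libraries of both groups, so the group difference adds to the spread within the new groups. Few or no called genes are therefore built into those splits and do not bear on chance. The real C4-2 split was 1 of 10 with as many genes (7557, highest other 0 by edgeR, with 24 to 129 genes at an unadjusted p under 0.05 in the others), and 1 of 10 with as many lists (14, highest other 10). The real 22Rv-1 split was 1 of 10 with as many genes (6467, highest other 0 by edgeR, with 75 to 205 at an unadjusted p under 0.05), and 1 of 10 with as many lists (21, highest other 12). For the 1999 genes that changed in opposite directions, 1 of 200 pairs of splits and orientations gave as many, and the highest other, 1707, was the pair with the 22Rv-1 labels exchanged. With a line regrouped edgeR gave 0, and at most 62 genes at an unadjusted p under 0.05 in both, which shows only that the groups of each line differ. The direction rests on 2 pairs, the real and the exchanged one, too few for a share under 0.05.

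For the difference between responses, 2 of 40 draws of the labels within lines gave as many genes as the real 7151, so chance was not excluded by this count. The other draw (7211) exchanged the C4-2 labels, which keeps all groups apart and gives the contrast aligned on the level of ARv7. Of 38 draws that regrouped a line the highest was 3775. Of 32 that regrouped both lines it was 0 by edgeR, and at most 330 genes had an unadjusted p under 0.05. Regrouping a line mixes its groups, as in the splits, so the lower counts of these draws do not bear on chance.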

How the results depend on the processing

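Total counts, libraries without ribosomal protein and mitochondrially encoded genes, and repair lists without cell-cycle-linked members were chosen after seeing the data. Counts of called genes stayed within 1.5 times the reported value under the settings run, with the exceptions given next. glmTreat against a fold of 1.2, which asks for a larger change by construction, called 4661 genes in C4-2 (2496 higher and 2165 lower) and 2862 in 22Rv-1 (1581 and 1281). Limma on log2(FPKM + 1) called 2237 lower genes in C4-2, where FPKM is scaled to the library total. Total counts with no scaling factor gave 2523 lower genes there, against 3776 with TMM. The median log2 change was 0.11 with limma on FPKM, 0.152 with total counts and 0.005 with TMM. The lower count thus goes with the scaling, and other differences of the limma fit were not tested. With changes of at least 2-fold, a stricter choice by construction, 108 genes moved in opposite directions and 77 in the same.

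Camera with an estimated correlation called 2 lists in C4-2 (2 higher, 0 lower, 1 lower at an unadjusted p under 0.05) and 1 in 22Rv-1 (0 higher, 1 higher at an unadjusted p under 0.05, and 1 lower). Fry, which tests whether a list moves on balance one way without comparing it with other genes, called 33 (17 higher, 16 lower) and 35 (17 higher). Without cell-cycle-linked members there were 9 lists in C4-2 (5 higher) and 12 in 22Rv-1 (5 higher, 7 lower). Members were removed only from the repair and checkpoint lists. Of 4 such lists called in each line, 4 lost the call in C4-2 and 3 in 22Rv-1, in part because shorter lists are harder to call. The other losses were in lists that kept all members, through the adjustment over lists. In 22Rv-1 a replicate block left 5 higher lists, and leaving out 1 library 5 to 8. The 6 lists lost with the block had camera adjusted p from 0.0584 to 0.0858. Same-number libraries did not correlate (-0.057 to 0.015), so the block removes degrees of freedom; the cause was not tested further.

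DESeq2 called 7008 genes in C4-2, 6820 of them shared with edgeR in the same direction, and 5707 in 22Rv-1, 5519 shared. Leaving out 1 library gave 6673 to 7870 genes in C4-2, 5793 to 6532 in 22Rv-1, 1810 to 2061 in opposite directions, 1494 to 1801 in the same, and 6658 to 7218 for the difference between lines. It gave 13 to 15 lists in C4-2 and 15 to 20 in 22Rv-1. Of 3353 values of named genes over settings in C4-2, 82 lost the call and 0 reversed. In 22Rv-1 101 of 3347 lost it and 0 reversed. Only called genes entered, most of them named for a small adjusted p or a large change, so few losses are in part built in. Genes that a setting did not test are not counted. Genes changed 1.2-fold were mostly missed on simulated data, where far fewer genes changed, the adjusted threshold was stricter and the spread was smaller. How many small changes were missed in the real data is therefore not known.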

Other observations

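Some genes changed at least 2-fold in the same direction in both comparisons, and those named here were chosen after their values were seen. TXNIP, which encodes an inhibitor of thioredoxin that is induced by glucose, rose from 13.9 ± 0.976 to 270.1 ± 9.94 CPM (SD, n = 3) in C4-2 with ARv7 and from 11.2 ± 1.66 to 99.3 ± 5.46 CPM in depleted 22Rv-1 cells. SEMA3C, a secreted semaphorin, rose 2.46-fold and 4.72-fold. RELN fell 3.68-fold and 7.82-fold, and the metallothionein gene MT2A fell 4.21-fold and 3.94-fold. ANXA1, an annexin that restrains inflammation, rose 6.62-fold and 10.1-fold from low levels. BCAT1, which starts the breakdown of branched-chain amino acids, fell 2.26-fold and 2.13-fold. edgeR adjusted p was 3.03e-06 or less for each of these genes in C4-2 and 6.46e-08 or less in 22Rv-1.

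SCD, the desaturase that makes oleic acid, fell from 1733 ± 67.7 to 699 ± 12.4 CPM in C4-2, where the list of fatty acid synthesis was not called (9 fell and 5 rose of 16; camera adjusted p = 0.14). TSC22D3, a glucocorticoid-induced leucine zipper gene, fell from 1821 ± 104 to 247 ± 5.99 CPM in C4-2. NFKBIA, which encodes an inhibitor of NF-kB, fell from 348 ± 15.1 to 67.6 ± 2.29 CPM. In C4-2 the list of glucocorticoid-induced genes was not called (6 fell and 4 rose of 13; camera adjusted p = 0.492). Nor was that of inflammatory NF-kB targets (3 fell and 4 rose of 10; camera adjusted p = 0.913).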
